A study of Mus musculus with 4 samples.

How the data were processed

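Single-cell RNA sequencing was measured in 4 libraries, each from live-sorted cells of 1 untreated end-point medulloblastoma of a Ptch1+/- mouse irradiated at birth, per the labels. The labels number the tumours 1 to 4 and do not state separately that each came from a different mouse. Suspensions had been frozen viably, thawed with DNase, stained with propidium iodide or DAPI, sorted and run on the 10x Genomics platform, per the labels' protocols. Cell Ranger, Seurat and the build mm10 were named in the submitters' processing notes, and their versions were not given in the sources used here. The deposited values were log2 values, log2(UMI count / size factor + 1), with size factors averaging 1 in each file. That form was read from the values themselves, and the tool that gave the size factors was not given in the sources used here. Every deposited value fell on a whole multiple of 1 step per cell within 1e-08, so the UMI counts could be worked out from the files. The file of tumour 1 listed 33219 genes, and those of tumours 2, 3 and 4 listed 14833, 13622 and 15359, which were genes seen in at least 5 cells. All 4 files shared 13149 genes. The files gave genes by symbol, and positions came from the annotation of GRCm38.p6, the assembly behind mm10, in which 177 of 179 symbols looked up were found. The handling of reads that map to several genes was not given in the sources used here, so Ptma, Npm1, H2afz, Hmgn2, Stmn1, Tuba1a, H2-K1, H2-D1 and the ribosomal protein genes, which have near-identical copies, are uncertain.

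Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, a filter that removed 0 of the 6509 deposited cells. Scrublet (in scanpy 1.11.5), run per tumour, called 20 doublets. That is 0.307% of cells against 100 expected at 0.8% per 1000 cells, so doublet calling may have missed most doublets. Doublets may therefore remain among the 6489 cells analysed, and whether some had been removed before deposit was not tested. Clusters were made with scanpy 1.11.5 and leidenalg 0.10.2 from 1000 highly variable genes, chosen per tumour and centred and scaled within tumour, with 30 principal components, 15 neighbours and resolution 1. The 420 measured genes of the report lists were kept out of the clustering. Other cell type markers were free to enter it, so the names of clusters are not independent of the clustering. The 20 clusters were named from lists of marker genes by their CPM, and names end in "-like" because they rest on transcripts alone. The thresholds for naming were set, and revised, after the clusters had been seen and before any gene was tested. Clusters whose markers met no threshold stayed unnamed, as did those whose 10 leading genes held no marker of their class or more markers of another, and unnamed clusters held 25.2%, 2.51%, 3.02% and 10.6% of the cells of tumours 1 to 4. Progenitor-like cells joined granule progenitor-like clusters, cycling-like clusters and clusters of mixed phase, and the last of these held 2.63%, 4.25%, 8.01% and 24.2% of the cells. The lists for oligodendrocyte precursors and oligodendrocytes were joined as oligodendrocyte lineage-like.

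Comparisons, lists, the rule for named genes and the alternative settings were fixed before the data were examined, with exceptions. The CPM sums and the removal of the expected share of doublets were 2 settings added later. The plan also joined only granule progenitor-like and cycling-like clusters as progenitor-like, and the mixed-phase clusters were added to them later. Because the deposited values were on a log scale, the count-model test chosen first gave way to the test set down for such values. This was limma 3.58.1 in R 4.3.3 with statmod 1.5.0, on the mean log2 value per tumour and class, with tumour as a block, variance trend and robust moderation, and a Benjamini-Hochberg adjusted p threshold of 0.05. All adjusted p-values of genes come from limma, and "difference" means the difference in mean log2 value between classes, with its SE. The moderation borrows variance across genes. With 3 or 4 tumours very small p-values therefore rest largely on that shared variance and do not measure agreement between tumours. They should not be ranked across comparisons. Tumour is the block because both classes of a pair came from the same tumour. A tumour entered with at least 10 cells in each class, and at least 3 tumours were needed. Genes listed in all 4 files and detected in at least 5% of cells of either class were tested. In the first 4 comparisons the clustering and marker genes were left out. Levels are given as CPM, the summed UMIs of a gene scaled to a common total, as means over tumours. Because a mean of log2 values depends on the depth of the cells, each comparison was repeated with log2 CPM of summed UMIs (pseudocount 10, chosen after the data had been seen). As planned, the first 4 were also repeated with every cell thinned to 4900 UMIs, the 20th percentile rounded down to a multiple of 100, and the Olig2 and Sox2 ones without thinning. In the first 5 comparisons the median over all genes stayed within 0.059 of 0 in each repeat. For Olig2 and Sox2, progenitor-like cells with at least 1 UMI before thinning were compared with those with none, on thinned values, and 1258 of the 6489 cells were too shallow for it. The gene that defined the cells was not tested.

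The 17 lists were the SHH pathway, neural stem and glial regulators, the Notch pathway, G1/S and DNA replication, cell cycle exit and quiescence, p53 targets, synaptic and excitability genes, axon guidance and migration, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrial transcripts, immediate early and dissociation stress genes, interferon response and antigen presentation, chromatin regulators, extracellular matrix and adhesion in glia, and lipid and cholesterol synthesis. They were tested with limma's camera at a preset correlation of 0.01, adjusted over all 102 tests of 17 lists in 6 comparisons. With the correlation estimated from the data, none of the 39 list calls held, and the lowest adjusted p was 0.520. Named genes were the 8 with the highest and the 8 with the lowest difference among those past the threshold, with a mean log2 CPM of at least 5 and the same direction in every tumour, and up to 3 members past the threshold from each list. Predicted genes, ribosomal protein genes and mitochondrial genes were passed over among the first. Gli1, Gli2, Hhip, Mycn, Sox2 and Olig2 were named wherever tested. Spop, Ung, Dnmt1 and Eed in cycling-like cells, Cxcr4 in neuron-like cells and Cd63 and Sqle in oligodendrocyte lineage-like cells fall outside this rule and were chosen after their values were seen. Ptch1 was too rarely detected to be tested. Results for some genes that the rule takes in are not reported here.

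Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error only, as do limits of 3 counts for a count of 0. Numbers were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The tests were tried on simulated data, progenitor-like cells of each tumour split at random into 2 groups, in which 200 genes had been changed. Such groups lack the differences in depth and make-up between real classes, and how these vary between tumours. The values that follow hold for that setting and do not describe the real comparisons. The share of genes changed 2-fold that was recovered was 75.0% over 10186 genes for the neuron-like, 83.3% over 10173 for the cycling-like, 25.4% over 10408 for the astrocyte-like, 57.8% over 9826 for the oligodendrocyte lineage-like, 86.4% over 8097 for the Olig2 and 41.3% over 8269 for the Sox2 comparison. Of genes changed 4-fold, 57.7% were recovered in the cycling-like comparison, fewer than at 2-fold, while every other comparison recovered more at 4-fold. Calls among unchanged genes numbered 0, 0, 0, 2, 6 and 0. Alternatives covered the filters, the block, doublet removal, the clustering, a split of the UMIs into a part for clustering and a part for testing, thinning, scaling and leaving out each tumour. Of the bounds that decide the tests of explanations, those for depth, for oligodendrocyte lineage-like doublets and for immune RNA were written before the results were seen and all others after. The tests of eGFP, of muscle RNA and of astrocyte-like doublets were changed or extended after they had first run.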

Results

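The data were single-cell transcriptomes of 4 medulloblastomas of the Sonic hedgehog (SHH) subgroup, tumours that arise from granule neuron progenitors of the cerebellum. The mice were heterozygous for Ptch1, which encodes the receptor that holds the pathway off, and all tumours formed 1 untreated group, so cells were compared within tumours. Tumours 1 to 4 gave 798, 2589, 1229 and 1893 cells, with 19446245, 23439893, 10458431 and 18242667 UMIs in total. Cells of tumour 1 were the deepest, with a median of 15284 UMIs and 4094 genes per cell. The medians were 7754, 6799 and 7825 UMIs in tumours 2, 3 and 4. The median share of mitochondrial UMIs lay between 2.30% in tumour 4 and 3.65% in tumour 1.

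Ptch1 (chromosome 13, 63508328 to 63573460, GRCm38.p6) was close to undetected, with 9, 5, 5 and 10 UMIs in tumours 1 to 4, or 0.429 ± 0.148 CPM (SD, n = 4). The libraries read the ends of transcripts and the labels do not give the deleted part, so this value checks no genotype. Genes that the SHH pathway drives were present in all 4 tumours. Gli1 (chromosome 10, 127329882 to 127341579), the transcription factor that the pathway induces, had 43.1, 56.3, 61.6 and 14.7 CPM, and Gli2, which carries the signal to the nucleus, had 18.1 ± 5.16 CPM (SD, n = 4). Mycn, which keeps granule progenitors dividing, had 226, 384, 524 and 68.5 CPM. Atoh1, the factor that specifies those progenitors, had 150, 213, 314 and 59.1 CPM. Within progenitor-like cells Gli1 was at 31.2 CPM in tumour 4 against 50.3, 67.2 and 70.0, but 455 of its 471 progenitor-like cells were of mixed phase. In the mixed-phase cells alone Gli1 was at 32.4 CPM in tumour 4 against 41.1, 43.1 and 36.9 in tumours 1 to 3. Those of tumour 4 formed a cluster of their own, apart from the 21, 110 and 98 cells of tumours 1 to 3, so the cells compared may differ in kind. The proliferation gene Mki67 had 104 ± 47.5 CPM, Rbfox3, which marks mature neurons, 89.1 ± 37.8, and Gfap, the intermediate filament of astrocytes, 46.9 ± 23.3 (SD, n = 4). In progenitor-like cells alone Rbfox3 was at 63.0, 114, 107 and 74.5 CPM and Gfap at 57.6, 24.5, 71.6 and 51.2 in tumours 1 to 4. The tumour values of these genes therefore do not measure mature neurons or astrocytes. Olig2, a regulator of oligodendrocyte progenitors, had 21.2 ± 12.1 CPM and Sox2, a neural stem cell factor, 4.60 ± 0.682. C1qa, a complement gene of microglia and macrophages, had 171, 114, 54.1 and 765 CPM. Xist, made from the inactive X chromosome, was listed for tumours 1 and 4, at 1590 and 820 CPM. The Y-linked Ddx3y was at 53.8 and 64.9 CPM in tumours 2 and 3, at 0 UMIs in tumour 1 and not listed for tumour 4.

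Progenitor-like cells made up 53.8% (95% interval 50.2 to 57.3), 71.8% (70.0 to 73.5) and 75.8% (73.3 to 78.2) of tumours 1 to 3 and 25.04% (23.1 to 27.1) of tumour 4. The 3 named immune classes together made up 53.2% (50.9 to 55.4) of tumour 4 against 11.4%, 5.65% and 1.14% of tumours 1 to 3. In tumour 4 these were myeloid-like (24.7%), neutrophil-like (19.9%) and T and NK cell-like cells (8.51%). Unnamed clusters led by dendritic cell genes held a further 133, 44 and 21 of its 1881 cells. No neutrophil-like cell was found among the 1224 of tumour 3, which allows a share of up to 0.245% by a limit of 3 counts, and 0.301% by the exact interval. Neuron-like cells made up 7.27%, 18.99%, 15.2% and 7.39%. Glia were rare in the main clustering, with 1.19 ± 0.491% astrocyte-like and 1.82 ± 1.299% oligodendrocyte lineage-like cells (SD, n = 4). Some shares depended on the clustering. At resolution 0.5 tumour 4 had 1.06% progenitor-like, 0.160% neuron-like and 41.9% unnamed cells, and its myeloid-like share was 14.6% at resolution 2 and 14.9% when clustered on its own. The progenitor-like share of tumour 1 was 32.3% at resolution 2 and 38.8% without doublet removal. Its astrocyte-like share was 10.0% when clustered on its own, and its oligodendrocyte lineage-like share 16.5% at resolution 0.5. The live sort and the freezing act on cell types in ways these data cannot measure, so shares describe the sequenced cells.

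**Figure D1:**
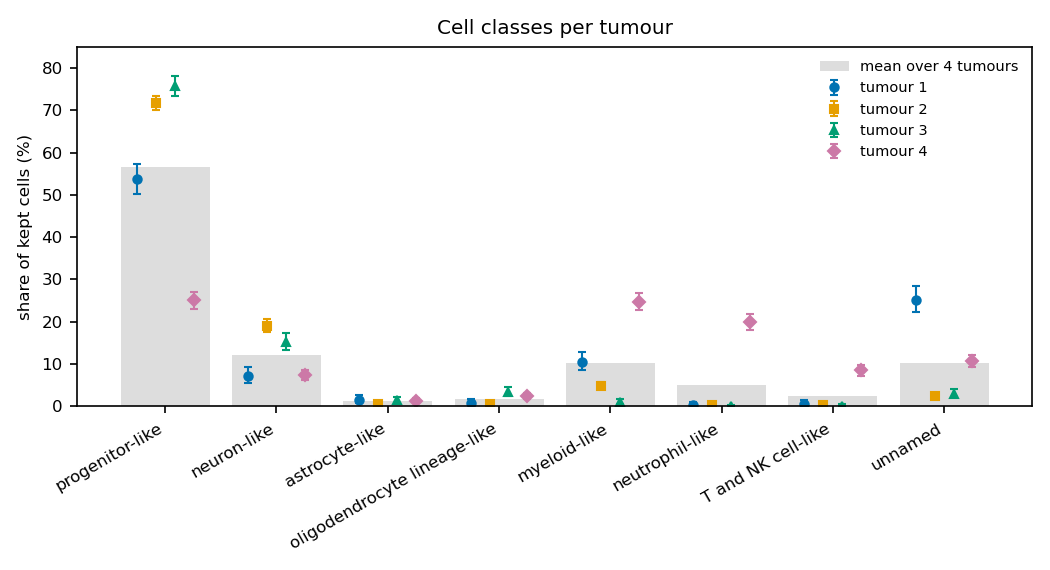
Share of kept cells in each class, in percent, with 1 point per tumour and its exact 95% binomial interval, and bars for the mean over the 4 tumours. Progenitor-like cells were at 53.8%, 71.8% and 75.8% in tumours 1 to 3 and at 25.04% in tumour 4, where neutrophil-like cells reached 19.9%.

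Neuron-like cells were compared with progenitor-like cells because granule progenitors mature into granule neurons, and whether the neuron-like cells arose from the tumour was not tested. In neuron-like cells Map1b (chromosome 13, 99421464 to 99516602), which stabilises microtubules in growing axons, was higher by 1.72 (SE 0.12, n = 4; 1178.5 against 344 CPM). Elavl3 (chromosome 9, 22015005 to 22052146), a neuronal RNA-binding protein, was higher by 1.52 (SE 0.08; 684 against 211 CPM), and Rab3a, a GTPase of synaptic vesicles, by 1.64 (SE 0.12; 443 against 73.5 CPM). Lower were Ran, which drives nuclear transport, with a difference of -1.12 (SE 0.09; 696 against 1368 CPM), and Rrm2, which makes deoxynucleotides, with -0.96 (SE 0.09; 55.5 against 237 CPM). Each of these 5 genes kept its direction in 4 of 4 tumours, with limma adjusted p-values from 1.99e-05 for Elavl3 to 0.000111 for Rrm2.

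Genes of the SHH pathway were lower in neuron-like cells, with 7 of 10 tested members past the threshold over all genes and 9 lower and 1 higher when adjusted over the list alone, against 8 lower and 1 higher with CPM sums and 6 and 1 with thinned cells. Among them were Gli1 (difference -0.27, SE 0.05, adjusted p = 0.00416; 22.2 against 54.7 CPM), Gas1, a co-receptor for the hedgehog ligand (-0.45; 17.1 against 72.8 CPM), Gli2 (-0.18) and Hhip, which binds the ligand (-0.14). The list had a median difference of -0.23 and camera gave adjusted p = 0.00242, and adjusted p = 0.632 with an estimated correlation. Mycn did not pass the test (difference -0.28, adjusted p = 0.0964), nor did Sox2 (-0.02, adjusted p = 0.299) or Olig2 (-0.08, adjusted p = 0.0618). The replication genes fell almost as a whole: 23 of 24 G1/S and DNA replication genes were lower over all genes, and 23 adjusted over the list alone, with a median of -0.44. Camera gave them adjusted p = 1.7e-13, and adjusted p = 0.570 with an estimated correlation. The progenitor-like class includes clusters named cycling-like by cell cycle markers, so this fall is in part built into the classes. The same holds for these genes in the astrocyte-like and oligodendrocyte lineage-like comparisons below. Synaptic and excitability genes went the other way, with 20 of 24 higher over all genes and 21 adjusted over the list alone, among them the glutamate receptor gene Grin2b (0.46; 75.0 against 17.0 CPM). That list had a median of 0.15 and camera adjusted p = 2.12e-11, and adjusted p = 0.570 with an estimated correlation.

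Of 14 axon guidance and migration genes, 6 rose over all genes and 6 adjusted over the list alone, led by Sema6a, which steers migrating granule cells (0.79; 156 against 42.7 CPM), while Cxcr4, the chemokine receptor of granule progenitors, fell. Camera gave the list adjusted p = 0.0373, and adjusted p = 0.632 with an estimated correlation. In the Notch pathway 4 of 10 members fell over all genes and 6 adjusted over the list alone, led by the target gene Hey1 (-0.62; 136 against 234 CPM). With thinned cells 2 of 6 fell. Camera gave adjusted p = 0.0168, and adjusted p = 0.570 with an estimated correlation. Ribosomal protein genes were lower in 77 of 78 cases over all genes and in 77 adjusted over the list alone (median -0.50, camera adjusted p = 2.26e-24, and adjusted p = 0.632 with an estimated correlation). Oxidative phosphorylation genes were lower in 32 of 87 cases over all genes and 33 adjusted over the list alone (median -0.13, camera adjusted p = 4.57e-06, and adjusted p = 0.710 with an estimated correlation). With CPM sums 17 of them were lower and 2 higher (median -0.03), and with thinned cells 11 were lower (median -0.02). Glycolysis genes went both ways, with 4 higher and 7 lower of 16, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.313). Ldha, which makes lactate, was lower by a difference of -0.62, and Ldhb, which favours its use, was higher by 0.55. The cell cycle exit list had 5 members higher and 3 lower of 14, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.116). Its members included Btg1, an antiproliferative gene (0.67; 502 against 295 CPM), and Cdkn1b, an inhibitor of cyclin-dependent kinases (0.34). Chromatin regulators also divided, with 3 higher and 5 lower of 18 by either adjustment, adjusted over the list alone or over all genes (camera adjusted p = 0.957), and with 6 and 6 with CPM sums and 5 and 4 of 17 with thinned cells. Chd7, a remodeller needed in granule cells, was higher by 0.83 (426 against 213 CPM), and Ezh2, the Polycomb methyltransferase, had a difference of -0.38. Neural stem and glial regulators had 3 higher and 6 lower of 17, or 3 and 7 adjusted over the list alone, with a median of -0.07, a mean of 0.06 and a downward test (camera adjusted p = 0.677), and Nfib, a factor of granule cell maturation, was higher by 1.04 (1831 against 935 CPM). Of the p53 targets 1 was higher and 3 were lower of 12, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.298), and of the mitochondrial transcripts 0 of 14 passed by either adjustment, adjusted over the list alone included (camera adjusted p = 0.850). Their median of -0.02 turned to 0.14 with CPM sums, with 4 higher, and to 0.08 with thinned cells, with 2 higher.

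In all, limma placed 3261 of 9835 tested genes past the threshold, 1412 higher and 1849 lower in neuron-like cells. The balance of directions depended on the scaling, with 2276 higher and 1758 lower with CPM sums and 1433 higher and 1108 lower with thinned cells. Without the block 0 genes passed and 522 had an unadjusted p under 0.05, and without tumour 2 the count was 2079.

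**Figure D2:**
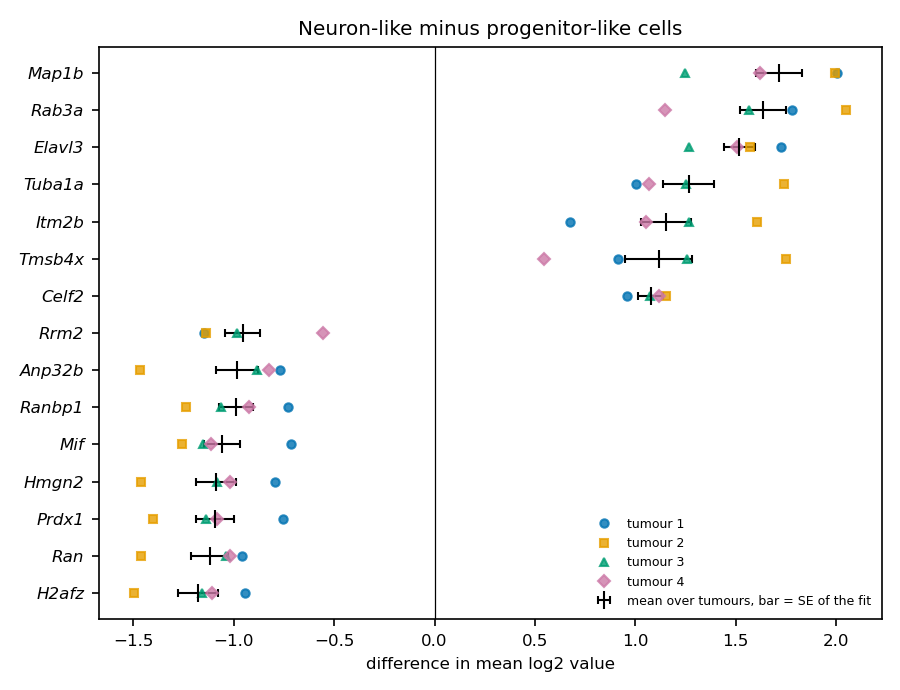
Difference in mean log2 value between neuron-like and progenitor-like cells for 15 named genes, with 1 point per tumour and a black tick for the mean with its SE (n = 4). Map1b, Rab3a and Elavl3 lie on the high side at 1.72, 1.64 and 1.52, and H2afz and Ran on the low side at -1.18 and -1.12.

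Cycling-like cells were compared with granule progenitor-like cells, both of them progenitor-like, in tumours 1 to 3. Tumour 4 had too few granule progenitor-like cells to enter. Smc4 (chromosome 3, 69004738 to 69034623), a subunit of condensin, was higher by 1.61 (SE 0.12, n = 3, adjusted p = 0.000346; 507 against 139 CPM), and Aurkb, a kinase of the mitotic spindle, by 1.12 (156 against 18.95 CPM). Rrm2 (chromosome 12, 24708254 to 24714146) was higher by 1.46 (SE 0.05, adjusted p = 3.03e-05; 389 against 142 CPM). Lower were Aldoa, an enzyme of glycolysis, with a difference of -0.81 (SE 0.06, adjusted p = 0.000215; 208 against 417 CPM), and Hey1 (chromosome 3, 8663359 to 8667038), a target of Notch, with -0.57 (173 against 320 CPM). These genes kept their direction in 3 of 3 tumours.

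Of the SHH pathway genes 4 of 11 were higher in cycling-like cells, namely Gas1 (0.46), Hhip (0.18), Gli1 (0.16, adjusted p = 0.0282; 68.6 against 58.4 CPM) and Spop, an adaptor for degradation of Gli proteins. Adjusted over the list alone 4 were higher and 1 lower, and the list as a whole did not pass (camera adjusted p = 0.539). Gli2 (0.05, adjusted p = 0.214), Sox2 (0.01, adjusted p = 0.473) and Olig2 (-0.05, adjusted p = 0.368) did not pass, and Mycn (-0.19, adjusted p = 0.0503) passed with CPM sums and with thinned cells. Of G1/S and DNA replication genes 20 of 24 were higher and 1 lower, or 22 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 4.82e-11, and adjusted p = 0.570 with an estimated correlation). The lower one was Ung, which removes uracil from DNA. Cycling-like clusters were named by cell cycle markers, so the rise of the replication genes is in part built into the classes. Of 17 glycolysis genes 7 were lower and 2 higher, or 8 and 2 adjusted over the list alone (median -0.07, camera adjusted p = 0.000775, and adjusted p = 0.570 with an estimated correlation). Ribosomal protein genes were lower in 40 of 78 cases, and in 59 adjusted over the list alone (median -0.17, camera adjusted p = 1.22e-29, and adjusted p = 0.632 with an estimated correlation), while 72 were lower with CPM sums and 70 with thinned cells. Chromatin regulators had 5 higher of 18, namely Ezh2 (0.74), Uhrf1, which recruits the maintenance methyltransferase (0.58), that enzyme's gene Dnmt1, and the Polycomb genes Suz12 (0.21) and Eed. Adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 0.119).

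Glial matrix and adhesion genes were lower in 2 of 12 cases, or 3 against 1 higher adjusted over the list alone (camera adjusted p = 0.00323, and adjusted p = 0.672 with an estimated correlation), while 6 were lower and 1 higher with CPM sums and 4 of 9 were lower with thinned cells. Of 22 synaptic and excitability genes 1 was lower, also adjusted over the list alone (camera adjusted p = 0.00902, and adjusted p = 0.570 with an estimated correlation), while 9 were lower and 1 higher with CPM sums and 3 of 18 were lower with thinned cells. Mitochondrial transcripts had 0 of 14 past the threshold, adjusted over the list alone as well, with a median of -0.10 (camera adjusted p = 0.000107, and adjusted p = 0.735 with an estimated correlation), while 10 were lower with CPM sums and 8 with thinned cells. Interferon response genes had 0 of 5 past it, adjusted over the list alone as well, with a median of -0.04 (camera adjusted p = 0.0322, and adjusted p = 0.695 with an estimated correlation), while 4 were lower with CPM sums and 0 of 4 with thinned cells. The immediate early and dissociation stress genes, which respond to handling of cells, had 2 higher and 3 lower of 13, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.751), and 3 and 5 with CPM sums. Limma placed 1619 of 9868 genes past the threshold, 1334 higher and 285 lower, against 1408 higher and 1785 lower with CPM sums and 852 and 755 with thinned cells. The count was 2968 without tumour 1, 970 without tumour 2, 580 without doublet removal and 40 without the block.

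Astrocyte-like cells, few in each tumour (12, 12, 18 and 25), were compared with progenitor-like cells. Sparc (chromosome 11, 55394159 to 55420080), a secreted matrix protein of astrocytes, was higher by 2.15 (SE 0.14, n = 4, adjusted p = 2.03e-20; 870 against 49.2 CPM). Id3 (chromosome 4, 136143822 to 136145392), an inhibitor of differentiation factors, was higher by 1.09 (SE 0.10, adjusted p = 8.69e-13; 255 against 5.18 CPM), Bcan, a brain proteoglycan, by 1.10 (SE 0.11, adjusted p = 8.73e-11; 294 against 29.9 CPM), and Slc6a11, a GABA transporter, by 1.07 (255 against 13.7 CPM). Olig2 was higher by 0.38 (adjusted p = 0.00124; 94.5 against 22.1 CPM), and Mycn lower, with a difference of -0.83 (adjusted p = 4.73e-05; 197 against 357 CPM), a call that was lost with thinned cells.

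Glial matrix and adhesion genes were higher in 8 of 15 cases, and in 8 adjusted over the list alone (median 0.28, camera adjusted p = 2.94e-18, and adjusted p = 0.520 with an estimated correlation). Neural stem and glial regulators were higher in 7 and lower in 2 of 19, or 9 and 6 adjusted over the list alone, with Hes5, a Notch effector, at 0.49 (camera adjusted p = 0.000156, and adjusted p = 0.570 with an estimated correlation), while 0 were lower with CPM sums or with thinned cells. Interferon response and antigen presentation genes were higher in 3 of 10 cases, and in 4 adjusted over the list alone, among them Ifitm3, an antiviral membrane protein (0.86; 271 against 25.9 CPM), and B2m, the light chain of MHC class I (0.47). Camera gave that list adjusted p = 8.54e-05, and adjusted p = 0.570 with an estimated correlation. Its member H2-K1 turned to -0.0095 with the expected doublets removed. Synaptic and excitability genes were higher in 5 of 26 cases, and in 5 adjusted over the list alone, with the glutamate receptor gene Gria1 at 0.57 (camera adjusted p = 0.000579, and adjusted p = 0.570 with an estimated correlation), against 3 of 18 with thinned cells. Gria2 of this list turned to -0.049 with 2000 clustering genes. Replication genes were lower in 12 of 24 cases, and in 16 adjusted over the list alone (median -0.32, camera adjusted p = 1.85e-08, and adjusted p = 0.570 with an estimated correlation). With CPM sums 8 were lower (median -0.41), and with thinned cells 3 (median -0.11). Of these genes Gins2, Mcm5 and Rrm2 turned to 0.11, 0.045 and 0.13 with 2000 clustering genes, and Gins2 and Rrm2 to 0.074 and 0.030 with the expected doublets removed. Chromatin regulators were lower in 4 of 18, and in 7 adjusted over the list alone (camera adjusted p = 0.00239, and adjusted p = 0.632 with an estimated correlation), against 2 with CPM sums and 0 with thinned cells. Ribosomal protein genes were lower in 75 of 78 cases, and in 77 adjusted over the list alone, but in 17 with CPM sums and 30 with thinned cells (camera adjusted p = 7.31e-34, and adjusted p = 0.586 with an estimated correlation). The SHH list had 1 lower of 10, Mycn, also adjusted over the list alone, and its median of -0.16 turned to 0.01 with thinned cells (camera adjusted p = 0.0338, and adjusted p = 0.721 with an estimated correlation). Gli1 (-0.20, adjusted p = 0.128), Gli2 (-0.14, adjusted p = 0.118), Hhip (0.01, adjusted p = 0.916) and Sox2 (0.11, adjusted p = 0.0981) did not pass.

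Limma placed 1132 of 10275 genes past the threshold, 343 higher and 789 lower, but 438 higher and 290 lower with CPM sums and 169 higher and 93 lower with thinned cells. The count was 720, 312 and 342 without tumours 1, 2 and 4, 10 without the block, and 0 when the expected share of doublets was removed (1387 genes had an unadjusted p under 0.05) or with 2000 clustering genes (1337 genes). Cells were clustered anew in the last 2 settings, so the class itself changed. In tumours 2 and 3 it held 57 and 91 cells with the expected doublets removed and 50 and 101 with 2000 clustering genes, against 12 and 18.

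Oligodendrocyte lineage-like cells were compared with progenitor-like cells in tumours 2 to 4, with 16, 41 and 46 cells, since tumour 1 had 7. Cspg5 (chromosome 9, 110243783 to 110262576), a proteoglycan of oligodendrocyte precursors, was higher by 3.09 (SE 0.17, n = 3, adjusted p = 4.13e-25; 1430 against 12.3 CPM). Olig1 (chromosome 16, 91269769 to 91271939), a factor of the same lineage, was higher by 3.07 (SE 0.19, adjusted p = 9.96e-17; 1611 against 39.3 CPM), and Olig2 (chromosome 16, 91225550 to 91228677) by 1.39 (SE 0.13, adjusted p = 4.99e-11; 330 against 13.6 CPM). Ptprz1, a receptor phosphatase of precursors, was higher by 1.54 (348 against 7.05 CPM), and Sox2 by 0.18 (adjusted p = 0.00106; 33.5 against 4.92 CPM). Rrm2 was lower, with a difference of -0.82 (adjusted p = 8.78e-07; 88.9 against 252 CPM).

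Glial matrix and adhesion genes were higher in 9 and lower in 1 of 13 cases, also adjusted over the list alone, and the lower one was the tetraspanin gene Cd63 (median 0.35, camera adjusted p = 4.99e-09, and adjusted p = 0.570 with an estimated correlation). Lipid and cholesterol synthesis, which myelin needs, had 4 of 15 genes higher, also adjusted over the list alone: Scd2 (0.50), Hmgcs1 (0.45), Scd1 and Sqle (camera adjusted p = 0.000686, and adjusted p = 0.570 with an estimated correlation). Synaptic and excitability genes had 6 higher and 1 lower of 27, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000536, and adjusted p = 0.570 with an estimated correlation). Interferon and antigen presentation genes had 4 of 9 higher, or 6 adjusted over the list alone, against 1 with CPM sums and 1 of 7 with thinned cells (camera adjusted p = 0.000713, and adjusted p = 0.570 with an estimated correlation). Replication genes were lower in 22 of 24 cases, and in 24 adjusted over the list alone, against 1 with CPM sums and 6 with thinned cells (camera adjusted p = 3.89e-12, and adjusted p = 0.649 with an estimated correlation). Their median of -0.40 was -0.89 with CPM sums and -0.18 with thinned cells, so the list lost calls while its median stayed below 0. SHH pathway genes were lower in 8 of 10 cases, Mycn (-1.17), Gli1 (-0.27), Gli2 (-0.12) and Hhip (-0.09) among them, and in 9 adjusted over the list alone, against 1 with CPM sums and 2 with thinned cells (camera adjusted p = 0.000645, and adjusted p = 0.672 with an estimated correlation). All 10 had a difference below 0 under each of the 3 scalings, with medians of -0.20, -0.76 with CPM sums and -0.12 with thinned cells. Ribosomal protein genes were lower in 77 of 78, also adjusted over the list alone, against 6 with CPM sums and 59 with thinned cells (camera adjusted p = 3.79e-41, and adjusted p = 0.632 with an estimated correlation). Their median of -1.26 was -0.58 with CPM sums and -0.63 with thinned cells. Chromatin regulators were lower in 6 of 18, or 7 adjusted over the list alone, against 0 with CPM sums and 2 of 17 with thinned cells (camera adjusted p = 0.0496, and adjusted p = 0.776 with an estimated correlation). Limma placed 2218 of 10327 genes past the threshold, 822 higher and 1396 lower, but 626 higher and 57 lower with CPM sums and 575 higher and 244 lower with thinned cells. The count was 669 without tumour 3 and 1300 without the block.

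Transcripts of Olig2, Sox2 and eGFP, a fluorescent protein sequence that the labels do not mention, had their highest means in oligodendrocyte lineage-like cells and the next in astrocyte-like cells. For Olig2 and eGFP these 2 classes kept this order in tumours 2, 3 and 4, but Sox2 in tumour 4 was at 32.8 CPM in the former and 45.8 in the latter. Olig2 had 330 ± 184 CPM in the former (SD, n = 3), 94.5 ± 33.8 in the latter, 22.1 ± 19.7 in progenitor-like and 10.7 ± 12.5 in neuron-like cells (SD, n = 4). Sox2 (chromosome 3, 34649995 to 34652461) had 33.5 ± 14.7, 25.2 ± 24.3, 4.85 ± 2.82 and 2.40 ± 1.41 CPM in the same order. Olig2 was detected in 25.4%, 3.02%, 4.85% and 15.9% of progenitor-like cells of tumours 1 to 4, against 2.38%, 0%, 0% and 0.645% of myeloid-like cells, which should lack it. Sox2 was detected in 8.62%, 4.42%, 1.19% and 7.01% of progenitor-like cells against 0%, 0.807%, 0% and 0.645% of myeloid-like cells. Median depths were 13958, 8650, 7050 and 8507 UMIs in progenitor-like and 10897, 6021, 8381 and 10338 in myeloid-like cells, of which tumour 3 had 12. The exact upper 95% limits of the myeloid-like shares were 8.34%, 2.93%, 26.5% and 1.87% for Olig2 and 4.30%, 4.41%, 26.5% and 1.87% for Sox2. In tumours 2 and 3 the intervals of both classes overlapped for Olig2 and for Sox2, so myeloid-like cells leave open whether detection there exceeds background. In tumour 2 the upper limits of neuron-like cells were 1.13% for Olig2 and 1.78% for Sox2. Both lay below the progenitor-like lower limits, 2.29% and 3.53%. After thinning, 0% of its 329 neuron-like cells had either gene, against 1.88% and 2.18% of its progenitor-like cells. These values argue against background shared by all cells as the whole cause in tumour 2, while tumour 3 stays open. Neuron-like cells had Olig2 in 25.9%, 0.204%, 6.45% and 4.32% and Sox2 in 6.90%, 0.611%, 1.08% and 2.88% of tumours 1 to 4, at median depths of 15946, 5585, 5037 and 9604 UMIs. After thinning, Olig2 was detected in 11.2%, 1.88%, 2.88% and 11.7% of progenitor-like cells.

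**Figure D3:**
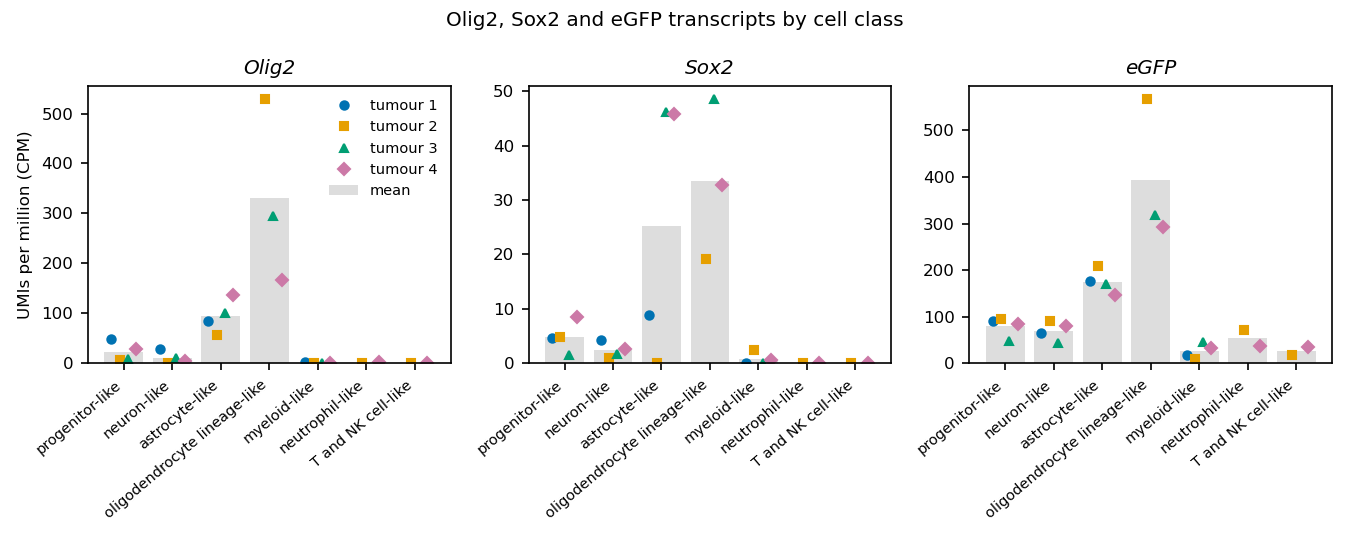
CPM of Olig2, Sox2 and eGFP by cell class, with points for tumours and bars for the mean over tumours with at least 10 cells of the class, which were 3 for the oligodendrocyte lineage-like class and 2 each for the neutrophil-like and the T and NK cell-like class. Olig2 lies at 330 CPM in oligodendrocyte lineage-like, 94.5 in astrocyte-like and 22.1 in progenitor-like cells.

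Progenitor-like cells with and without Olig2 were compared because Olig2 is a regulator of stem-like cells in this tumour type. With 109, 55, 39 and 70 detected cells, 22 genes were higher and 7 lower of 8175 tested. Etv5 (chromosome 16, 22381313 to 22439570), a transcription factor induced by FGF and MAP kinase signals, was higher by 0.32 (SE 0.04, n = 4, adjusted p = 2.62e-07; 126 against 36.0 CPM). Efhd2, a calcium-binding protein, was higher by 0.30 (SE 0.04, adjusted p = 1e-05; 143 against 54.7 CPM), Bcan by 0.20 (SE 0.03, adjusted p = 9.02e-05; 71.4 against 20.2 CPM) and Gas6, a ligand of TAM receptors, by 0.23 (adjusted p = 0.000223; 97.4 against 36.9 CPM). Igfbpl1, a gene of immature neurons, was lower, with a difference of -0.30 (SE 0.06, adjusted p = 0.0137; 457 against 618 CPM). Lhx1, a homeobox gene of developing neurons, had a difference of -0.18.

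Of 14 neural stem and glial regulators 3 were higher, Vim, an intermediate filament of radial glia (0.27, adjusted p = 0.0227), Sox9, a factor of glial fate (0.20, adjusted p = 0.0286), and Hes1, a Notch effector (0.21, adjusted p = 0.0227, higher in 3 of 4 tumours). Adjusted over the list alone 4 were higher (median 0.07, camera adjusted p = 2.12e-08, and adjusted p = 0.570 with an estimated correlation). In the Notch pathway 1 of 8 was higher, Notch1 (0.07, adjusted p = 0.0409), or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.570 with an estimated correlation). Of 11 glial matrix genes 2 were higher, Bcan and Sparc (0.18, adjusted p = 0.00388), or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.01e-05, and adjusted p = 0.570 with an estimated correlation). G1/S and DNA replication genes had a median of -0.05 with 0 of 24 past the threshold, adjusted over the list alone as well (camera adjusted p = 3.97e-06, and adjusted p = 0.570 with an estimated correlation). Ribosomal protein genes had a median of -0.02 with 0 of 78 past it, adjusted over the list alone as well (camera adjusted p = 0.000686, and adjusted p = 0.748 with an estimated correlation). Immediate early and dissociation stress genes had a median of 0.04 with 0 of 14 past it over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.000491, and adjusted p = 0.645 with an estimated correlation). SHH pathway genes had 0 of 10 past it over all genes and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.785). Gli1 (0.01, adjusted p = 0.963), Gli2 (-0.03, adjusted p = 0.780), Hhip (-0.00053, adjusted p = 0.995) and Mycn (-0.21, adjusted p = 0.134) did not pass.

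The sequence eGFP was among the 22 higher genes (0.17, SE 0.04, adjusted p = 0.0341; 117 against 70.9 CPM). The limma count of 29 genes was 11 without tumour 2 and 129 without tumour 3. It was 98 without thinning (88 higher, 10 lower), 0 without the block (179 genes had an unadjusted p under 0.05) and 0 without the filter on low values (834 genes).

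**Figure D4:**
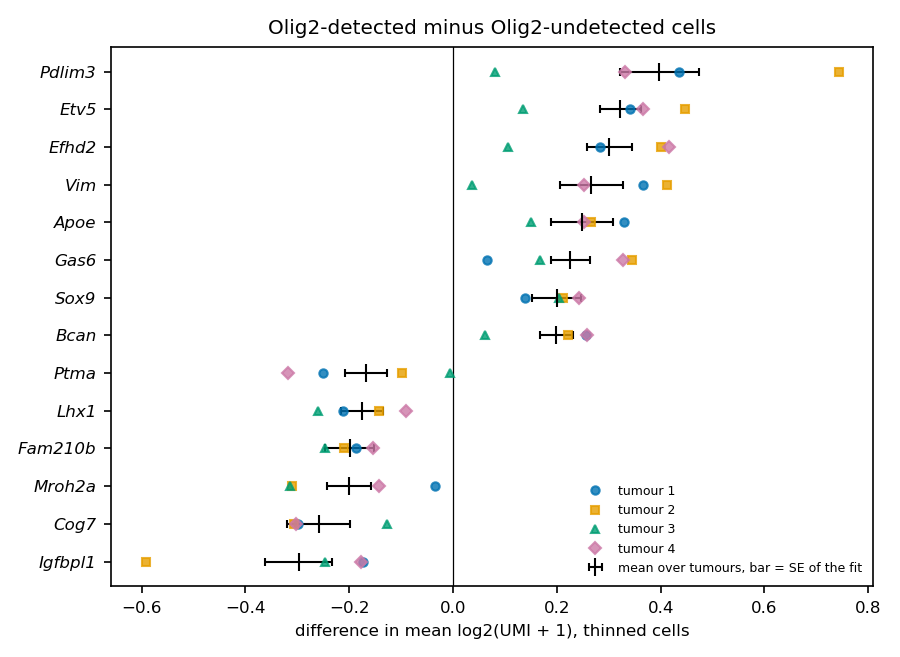
Difference in mean log2(UMI + 1) of thinned cells between progenitor-like cells with and without Olig2 for 14 named genes, with 1 point per tumour and a black tick for the mean with its SE (n = 4). Etv5 lies at 0.32 and Efhd2 at 0.30, and Igfbpl1 on the low side at -0.30.

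Progenitor-like cells with and without Sox2, compared for the same reason with 37, 80, 11 and 31 detected cells, gave no gene past the threshold. Limma called 0 of 8340 genes, and 460 had an unadjusted p under 0.05. Olig2 was at 54.4 against 20.9 CPM (difference 0.11, SE 0.04, n = 4, adjusted p = 0.849), higher in 3 of 4 tumours. Gli1 (0.05, adjusted p = 0.882), Gli2 (-0.03, adjusted p = 0.915), Hhip (0.03, adjusted p = 0.890) and Mycn (-0.14, adjusted p = 0.849) did not pass. Neural stem and glial regulators had a median of 0.05, with 0 of 16 past the threshold and 2 higher adjusted over the list alone (camera adjusted p = 0.00137, and adjusted p = 0.570 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.02, which turned above 0 without thinning, and 0 of 85 past it, adjusted over the list alone as well (camera adjusted p = 0.0201, and adjusted p = 0.570 with an estimated correlation). Ribosomal protein genes had a median of -0.02 and 0 of 78 past it, adjusted over the list alone as well (camera adjusted p = 0.0338, and adjusted p = 0.907 with an estimated correlation). The count was 1 without tumour 1 and 4 without tumour 3.

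Sox2 and Olig2 were found together in 0, 1, 0 and 6 thinned progenitor-like cells of tumours 1 to 4, against 0.671, 0.697, 0.173 and 1.87 expected if they were independent, so that only tumours 2 and 4 had more than expected. The log odds ratio, with 0.5 added to each count, had a mean of 0.70 ± 0.90 (SD, n = 4; exact sign-flip test, two-sided, p = 0.25), and with 0 such cells its sign rests on the 0.5. Leaving out 1 tumour gave means from 0.39 to 1.11. With 4 tumours this test cannot reach 0.05. In tumour 4 the odds ratio was 5.05 (95% interval 1.43 to 16.4). Without thinning 17, 9, 1 and 10 cells had both, against 9.40, 2.47, 0.533 and 5.25 expected. The odds ratios were then 2.76 (95% interval 1.301 to 5.82), 4.52 (1.88 to 9.80), 1.98 (0.0447 to 14.5) and 2.49 (1.01 to 5.75), but there cells differ in depth, which raises the detection of both genes together.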

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

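The comparison of each tumour with the other 3 was set beforehand, as was the test of immune RNA, while the test of eGFP against Olig2 was among the tests chosen only after the result was seen.

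Tumour 4 stood apart from tumours 1 to 3 by its immune cells. Its share of neutrophil-like cells was 19.9%, and the gap to the nearest other tumour was 0.979 of the whole range. For T and NK cell-like cells, at 8.51%, the gap was 0.945 of the range, and for C1qa, at 765 CPM, it was 0.836. Tumour 2 stood apart by a low share of astrocyte-like cells, 0.464%, with a gap of 0.832 of the range. That share was 1.93% with 2000 clustering genes, against 1.504% and 1.17% in tumours 1 and 4, and 2.25% with the expected doublets removed, against 1.39% and 1.34%, so tumour 2 was not the lowest there. Tumour 2 stayed the lowest at resolution 0.5 (0.348%), at resolution 2 (0.812%), without doublet removal (0.4635%) and with each tumour clustered on its own (0%). Of 22 values tested in this way 4 stood out, where chance gives about 1 in 20, and those 3 of tumour 4 describe the same immune cells and are not separate evidence.

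Genes of MHC class I, which presents peptides to T cells, were also higher in the progenitor-like cells of tumour 4 than in those of tumours 1 to 3: 130 against 69.1 ± 10.7 CPM (SD, n = 3) for H2-D1, 74.9 against 8.43 ± 9.16 for H2-K1 and 368 against 154 ± 52.4 for B2m, 3 genes chosen after their values were seen. In tumour 4, 455 of the 471 progenitor-like cells formed a cluster with no cell of tumours 1 to 3, so different clusters are compared. Free RNA from the many immune cells would need to make up 3.87%, 8.21% and 5.80% of the UMIs of the progenitor-like cells of tumour 4 to give the 3 levels. Genes made by immune cells alone showed shares between 2.61% for Lyz2 and 7.53% for Ptprc there. The smallest share needed was 0.514 of the largest share shown, so expression in the tumour cells cannot be told apart from free RNA, since both sets of shares overlap. That tumour cells near immune cells make more MHC class I may still hold, and no group of the design tests it.

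Transcripts matching eGFP, a fluorescent protein sequence that the labels do not mention, had 5682 UMIs, or 79.8 CPM, in the kept cells. They were highest in oligodendrocyte lineage-like cells (393 ± 152 CPM, SD, n = 3), then astrocyte-like cells (175 ± 25.8, SD, n = 4), progenitor-like cells (80.1 ± 21.3) and neuron-like cells (70.3 ± 20.8), against 26.3 ± 15.7 in myeloid-like cells. Neutrophil-like cells had 54.4 ± 24.8 and T and NK cell-like cells 26.3 ± 10.9 CPM (SD, n = 2). In tumour 3 the 12 myeloid-like cells were at 45.2 CPM against 48.8 in progenitor-like cells. A reporter that follows Olig2 could give the order from oligodendrocyte lineage-like to neuron-like cells, and eGFP was higher in Olig2-detected than in other progenitor-like cells of all 4 tumours. Olig2 was number 402 of 13148 genes when ranked by the difference in detection between progenitor-like cells with and without eGFP. That ranking decides nothing, because Olig2 was detected in 6.92% of the thinned cells and the first gene, Jun, in 68.5%, and a rarely detected gene can differ by few percentage points. Whether eGFP follows Olig2 stays open.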

How the results depend on the processing

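The tests with CPM sums and with the expected share of doublets removed were chosen only after the results were seen, and the others beforehand. Of 240 values of the main results under other settings 188 stayed close to the reported value, which for a count of genes means within 1.5 times. Of the others 37 were weaker, 9 stronger and 6 moved. Of 3799 values of the 261 named genes 2978 kept their call or their lack of one, 795 kept direction and lost the call, 13 gained it and 13 reversed. The setting without the cell filter is included and was bound to stay the same, since the filter removed 0 cells. Among the 2978 were 24 without a call that changed sign. Some comparisons rest on few cells, since astrocyte-like cells numbered 12 to 25 per tumour and Sox2 was seen in 11 progenitor-like cells of tumour 3. The cause was not tested for any change given here.

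For neuron-like cells the count of 3261 genes became 1881 with each tumour clustered on its own, 2074 when UMIs were split between clustering and testing, and 2079 to 3385 with a tumour left out. For cycling-like cells the count of 1619 became 3193 with CPM sums, 580 without doublet removal, 568 at resolution 2, 874 with split UMIs and 970 to 2968 with a tumour left out. For astrocyte-like cells the count of 1132 became 728 with CPM sums, 82 without the filter on low values, 210 at resolution 2, 0 with 2000 clustering genes (1337 at unadjusted p under 0.05), 19 with each tumour clustered on its own, 0 with the expected doublets removed (1387), 24 with split UMIs, 262 with thinned cells and 312 to 975 with a tumour left out. For oligodendrocyte lineage-like cells the count of 2218 became 683 with CPM sums, 1261 without the filter, 219 at resolution 0.5, 1462 with split UMIs, 819 with thinned cells and 669 to 1960 with a tumour left out. For Olig2 the count of 29 became 0 without the filter (834 at unadjusted p under 0.05), 98 without thinning, 464 over all neural cells, 81 with at least 2 UMIs and 11 to 129 with a tumour left out. For Sox2 the count of 0 became 1 over all neural cells and 0 to 4 with a tumour left out.

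Without the block, that is without the pairing of classes by tumour, the neuron-like, cycling-like, astrocyte-like, oligodendrocyte lineage-like and Olig2 comparisons gave 0, 40, 10, 1300 and 0 genes in limma, with 522 and 179 at an unadjusted p under 0.05 in the first and last. With an estimated correlation 0 of 17 lists passed in each of the 6 comparisons. The mean astrocyte-like share of 1.19% became 1.75% at resolution 2, 3.21% with 2000 clustering genes, 6.06% with each tumour clustered on its own and 3.11% with the expected doublets removed. The oligodendrocyte lineage-like share of 1.82% became 5.92% at resolution 0.5 and 0%, 1.01%, 3.27% and 0% in tumours 1 to 4 with each tumour clustered on its own, and the unnamed share of 10.3% became 21.5% at resolution 2.

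Reversed differences stood beside astrocyte-like cells, all but 1 of them. With 2000 clustering genes they were 0.11 for Gins2, -0.049 for Gria2, 0.030 for Hmgn2, 0.045 for Mcm5 and 0.13 for Rrm2. With the expected doublets removed they were 0.074 for Gins2, -0.0095 for H2-K1, 0.052 for Hmgn2, 0.0072 for Rbm3 and 0.030 for Rrm2. Clustering each tumour on its own gave 0.0025 for Ier2, and thinning gave 0.022 for Jund. The other was Ccng2 in oligodendrocyte lineage-like cells, 0.10 at resolution 0.5. Astrocyte-like cells at resolution 0.5, oligodendrocyte lineage-like cells with each tumour clustered on its own and Sox2 with at least 2 UMIs gave no value, because too few tumours had 10 cells. The count-model test and its own size factors were not run, because the test set down for log2 values was used, although UMI counts could be worked out from them.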

Other observations

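The tests of muscle RNA, of astrocyte-like doublets and of other splits of the columns were chosen only after the result was seen, and those of oligodendrocyte lineage-like doublets and of depth were chosen before.

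Myod1, the master regulator of skeletal muscle, was transcribed in progenitor-like cells of all 4 brain tumours, at 105, 68.2, 78.5 and 21.2 CPM in tumours 1 to 4. It was detected in 58.3%, 33.4%, 32.9% and 16.6% of these cells, against 8.33%, 2.42%, 0% and 0.645% of myeloid-like cells, at median depths of 13958, 8650, 7050 and 8507 UMIs and of 10897, 6021, 8381 and 10338 UMIs. Neuron-like cells had 42.0, 8.43, 27.5 and 15.5 CPM. The genes of this part were chosen after their values were seen, and no test was made on them. Tumour 1 also held 58 cells, 7.27% of its total, with a wider muscle program: Myog, a factor of muscle differentiation, stood at 3492 CPM against 51.4 in its progenitor-like cells, and the muscle actin gene Acta1 at 2247 against 10.6 CPM. The imprinted growth gene Igf2 and its neighbour H19 were high there too, at 1372 and 3327 CPM. H19 was at 124 CPM in progenitor-like cells of tumour 1 and at 0.877, 0.758 and 0.573 CPM in those of tumours 2 to 4. Neuron-like and myeloid-like cells of tumour 1 had 96.8 and 25.5 CPM of H19. Free RNA from the 58 cells as a source of H19 in these classes was not tested.

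Dendritic cell genes led 3 of the clusters that stayed unnamed. A cluster of 144 cells was led by Ccl17, Ccl22 and Ccr7, which guide T cells and dendritic cells, 44 cells of tumour 4 by Xcr1, a receptor of cross-presenting dendritic cells, and 34 cells by Siglech, a gene of plasmacytoid dendritic cells. A further unnamed cluster of 223 cells, 132 of them from tumour 1, was led by the neuronal genes Cntn2, Stmn2 and Neurod1 and had a median of 29351 UMIs, so that doublets among them were not excluded.

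For the muscle program of tumour 1, free RNA as the whole cause is argued against by its amount per cell. Over 27 muscle genes that neither entered the clustering nor led the 58 cells, UMIs per cell were a median of 20 times (lower quartile 9.50) those of the highest other class tested, though Myod1, not among them, had 3.46 times. Doublets of a muscle cell and a tumour cell stay open, since markers of granule progenitors stood at 0.278 of their level in progenitor-like cells of the tumour, between the bounds set for either outcome, and the median depth of 14708 UMIs was close to the 13958 of those cells. The 58 cells may therefore be muscle cells, tumour cells with a muscle program or mixtures, and no biological explanation was tested.

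For the genes that were higher in Olig2-detected progenitor-like cells, such as Etv5, Efhd2 and Sox9, both glial admixtures and depth are argued against for the set as a whole. If oligodendrocyte lineage-like cells or their doublets carried these genes in, Cspg5 should rise with them, yet it needed at most 0.0195 of the share that the risen genes needed in tumours 2 to 4, while tumour 1 had too few such cells for the test. For astrocyte-like cells, Sparc and Slc6a11 needed at most 0.113 of it, but these cells stay open for Sparc itself and for 8 other genes, Bcan, Vim and eGFP among them, whose rise needed at most 2 times the share of those 2 in at least 1 tumour. Against undetected cells matched for depth the median difference was at least 0.878 of that against all undetected cells, with 22, 22, 21 and 22 of 22 genes higher in tumours 1 to 4. The 22 genes were chosen as higher in these same detected cells, so the counts of direction were largely fixed and add no support. For the other genes a distinct state of the tumour cells may hold as a hypothesis, found and tested on the same data, and doublets of cells from unnamed clusters were not tested.

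Splits of the same columns into other groups, the real one included, were used to ask whether chance could give as many genes. For neuron-like cells 1 of 32 splits, the real one, gave 3261 genes and the highest other 0, and for astrocyte-like cells 1 of 32, with 1132 genes against 361. For Olig2 1 of 32 reached 29 genes, with 27 in the highest other. Only 8 of these splits part both classes of every tumour as the real one does, and the highest other of them gave 0, 0 and 14 genes. These 8 are too few for a share under 0.05. The others put both classes of some tumours into the same group, so with tumour as a block they rest on fewer tumours. The splits therefore cannot exclude chance here. Nor do they test how the clustering formed the neuron-like and astrocyte-like classes from the same cells. For Sox2 the real split gave 0 genes, which every split reaches by necessity, so the test decides nothing there. The highest other split gave 10. For cycling-like cells (1619 genes against 0, 1 of 10 splits) and oligodendrocyte lineage-like cells (2218 against 0, 1 of 10) the splits were too few for a share under 0.05.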
